A study of Ovis aries with 16 samples.

How the data were processed

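The deposited table held whole-number counts per mature miRNA or piRNA name for 16 libraries, made by the authors from QIAseq miRNA libraries of sheep serum and serum EVs. Per the labels' protocols, serum was spun at 300 xg, EVs of 70 to 1000 nm were collected on a size-exclusion column and eluted in 700 µl PBS, RNA was purified with an RNeasy kit and 1 ng of RNA entered each library. Per the submitters' processing notes, reads were converted with bcl2fastq 2.20.0.422 and the human build hg19 was used. The aligner, the counter, the miRNA annotation, any filter and the use of molecular identifiers are not given in the sources used here. Sheep reads were thus named by human entries, miRNAs of 1 family with near-identical sequences (let-7, miR-320, and miR-17 with miR-106) could share reads, and those members are uncertain one by one. The 1105 names comprised 1075 miRNA and 30 piRNA rows, and 4 rows shared 2 names. No human name was checked against sheep sequence, so a listed name does not show that sheep make that miRNA or piRNA. This holds for every name below, and a name may hold fragments of other RNAs. Counts were used as deposited.

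Groups came from the sample titles, and the letters A to F in the titles were read as animals. The labels do not say more about how samples relate, so p-values measure only the spread between these samples, which may in part be technical. The depth was 65537 to 639207 counts per library. Shares of counts are percent of a library's total, and values are mean ± SD over libraries. Wilson 95% intervals of the shares printed for single libraries reached at most 0.383 percentage points to either side of their centre, and they cover counting error only, since reads copied by PCR are not independent molecules.

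Each comparison was fitted on the groups it compares with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, filterByExpr with a minimum count of 10, Benjamini-Hochberg adjustment with a threshold of 0.05). TMM factors over all libraries ran from 0.278 to 2.94. The 5 comparisons were serum after against before surgery, EVs after against before, EVs against serum before, EVs against serum after, and the interaction over all 16 libraries. Adjusted p are from edgeR unless another tool is named, and fold changes are the fitted log2 fold changes with their SE. Of 19 lists with 265 names fixed in advance, those with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. The lists were red blood cell, liver, heart and skeletal muscle, endothelium, platelet, myeloid cell, lymphoid cell, smooth muscle, fibrosis, inflammation, hypoxia, let-7 family, miR-17 to miR-92 clusters, miR-320 family, epithelium, neuron, 14q32 cluster, other small RNA fragments and primate chromosome 19 cluster. Some miRNAs belong to several lists, for example miR-92a-3p to red blood cell and the miR-17 to miR-92 clusters, and most are expressed in more than 1 tissue. Whole-library measures were compared with 2-sided exact permutation tests of the difference of means, and the 28 p-values were adjusted together.

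The groups, tests, lists, alternatives and the rule for named miRNAs were fixed before the data were examined. The rule took, per direction, the 12 largest log2 fold changes among names past the threshold with a group mean of at least 100 CPM (TMM-scaled), or the 6 smallest p where none passed, and up to 4 members with the highest mean per list. Names outside it are marked as chosen after their values were seen. Each p from the fits was also recomputed with DESeq2 1.42.0, limma-voom, RLE factors, library totals, the red blood cell list or the most abundant name left out, no filter, a minimum count of 50, the animal as a block or random effect, all 16 libraries in 1 fit, thinning to 65537 counts and each library left out. Added after seeing the data were fits with the sets of shared zeros as a term, of names above 0 in every compared library, without piRNAs, within the 5 EV libraries that share zeros, without the other EV libraries, and without the serum library of the lowest total. For lists that passed only in an alternative, camera with an estimated correlation in the same alternative was also added then. Libraries were joined into sets of shared zeros by single linkage at a phi coefficient above 0.8. For after against before surgery, the sets as a term leave only sets that hold both times to inform the change. In serum this is animal B before against animals E and F after surgery, and in EVs it is the 5 libraries that share zeros. The animal as a block compares the times only within animals D and E, which leaves little to estimate the spread.

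Scaling mattered for the centre of all names. The median log2 fold change under TMM and under library totals was −0.20 and −0.93 in serum after against before surgery, −0.017 and −0.55 in EVs, 0.35 and 1.04 for EVs against serum before, 0.30 and 1.5 after, and 0.26 and 0.48 for the interaction. Fold changes are relative to the TMM centre.

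The pairing was checked as the correlation of deviations from the group means between libraries of the same letter. Before against after surgery it was 0.187 and 0.109 in serum of animals D and E and 0.418 and 0.121 in their EVs. Between serum and EVs of the same time it was 0.175, −0.138, 0.682, −0.297 and −0.0915 in animals A to E before surgery and 0.126, −0.0909 and −0.180 in animals D to F after it. Same letters were treated as the same animal because the titles name them alike, and the block stayed an alternative. The edgeR steps were tested on simulated counts with 200 names changed by known folds, drawn once with the spread fitted to these libraries and once with a small spread (dispersion 0.05 for every name). Recovery is the share of changed names that still passed the filter, so names lost to the filter are not counted as missed. Counts were drawn independently, without the sets of shared zeros and with all 200 names changed at once, so recovery in these libraries may be lower.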

Results

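Small RNAs were sequenced from the serum of sheep and from extracellular vesicles (EVs, membrane-bound particles released by cells) isolated from serum. Samples were taken before and after a single-stage Fontan operation, a surgery that routes systemic venous blood to the lungs without passing through a pumping ventricle. The 16 libraries fell into 4 groups: serum before surgery (n = 5, animals A to E), serum after surgery (n = 3, animals D to F), EVs before surgery (n = 5, animals A to E) and EVs after surgery (n = 3, animals D to F). Animal D was sampled on day 6 after surgery and animals E and F on day 7. The table held 1105 names, of which 1075 were miRNA and 30 were piRNA entries. All were human names that were not checked against sheep sequence. Library totals ran from 65537 counts in EVs of animal B before surgery to 639207 in serum of animal C before surgery. Serum totals before surgery were 158011, 552833, 639207, 76988 and 155815 counts in animals A to E, and those after surgery were 517833, 176789 and 262101 in animals D to F. EV totals were 67882, 65537, 567514, 276696 and 85449 before surgery and 473978, 160079 and 92810 after it.

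Red blood cell miRNAs made up much of every group. miR-486-5p, one of the most abundant miRNAs of red blood cells, took 26.4% ± 10.8 of counts (SD, n = 5) in serum before surgery and 27.8% ± 8.16 (n = 3) after it. Its share in EVs was 13.6% ± 10 (n = 5) before and 12.2% ± 3.32 (n = 3) after surgery. miR-16-5p, another red blood cell miRNA, took 12.3% ± 6.35 and 8.71% ± 4.92 in serum and 10.5% ± 4.24 and 9.89% ± 6.36 in EVs, before and after surgery respectively. miR-451a, which is made in red blood cell precursors, took 0.911% ± 0.713 and 0.191% ± 0.0424 in serum and 1.24% ± 1.87 and 0.553% ± 0.309 in EVs. miR-223-3p, a miRNA of neutrophils and monocytes, took 1.29% ± 0.989 and 0.929% ± 0.403 in serum and 1.35% ± 0.717 and 1.36% ± 0.870 in EVs. miR-21-5p, widely studied in fibrosis, took 0.607% ± 0.160 and 0.477% ± 0.310 in serum and 1.06% ± 0.364 and 0.735% ± 0.369 in EVs. miR-122-5p, the dominant miRNA of hepatocytes, took 1.65% ± 2.55 and 3.41% ± 2.38 in serum and 2.43% ± 3.20 and 10.8% ± 9.16 in EVs.

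**Figure D1:**
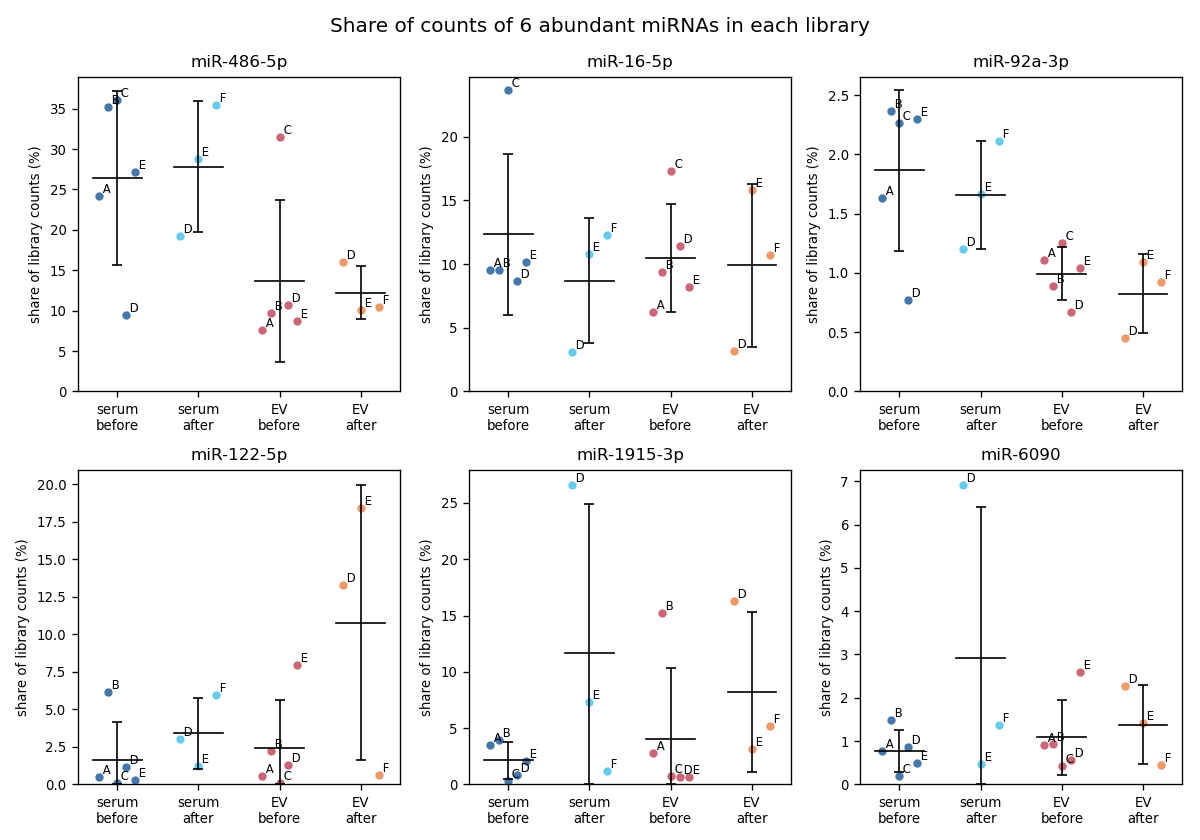
Share of library counts (percent, linear axes) of 6 abundant miRNAs in each library, by group, with animal letters. Horizontal lines are group means and vertical bars are SDs, which stop at 0 on the lower side. miR-1915-3p reached 26.6% in serum of animal D after surgery, above the other 7 serum libraries, and miR-486-5p reached 31.5% in EVs of animal C before surgery.

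The names with a count of 0 fell into 8 sets of libraries that shared nearly all of their zeros. Serum of animal B before surgery and serum of animals E and F after surgery had 524 names at 0 in common, and the smallest sum of any other name over these 3 libraries was 24. EVs of animals A, B and E before surgery and of animals E and F after surgery had 292 names at 0 in common, and the smallest sum of any other name over these 5 libraries was 42. Serum of animals A and E before surgery shared 318 zeros, and serum of animals C and D before surgery shared 224. The other 4 libraries each stood alone, which were serum of animal D after surgery, EVs of animals C and D before surgery and EVs of animal D after it. The phi coefficient between zero patterns was at least 0.895 within a set and at most 0.483 between sets, and no set held both serum and EVs. A count of 0 therefore means listed at 0, with no limit of detection given for it. Above 0 in all 16 libraries were 375 names.

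**Figure D2:**
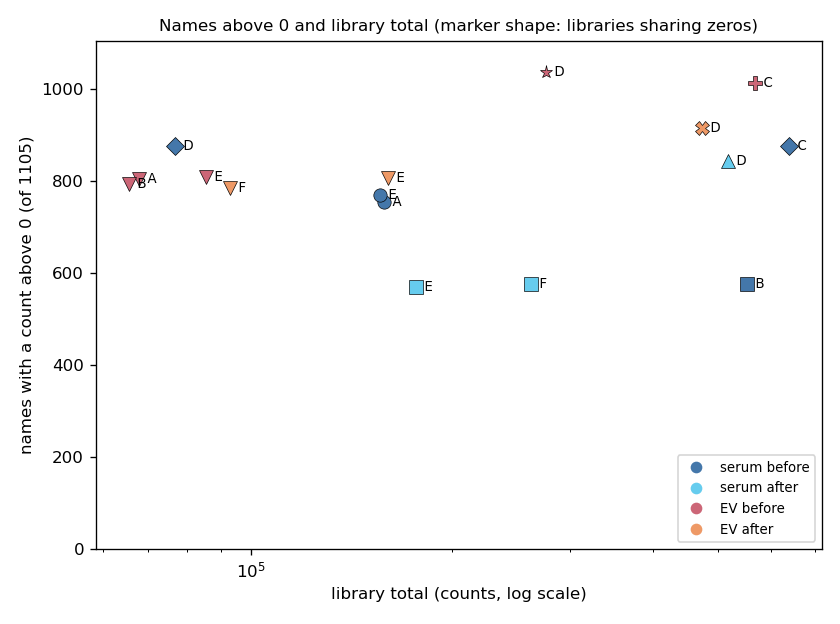
Number of names with a count above 0 (of 1105) against the library total (counts, log scale), labelled by animal. Colours are the 4 groups and marker shapes are the 8 sets of libraries that share zeros. The 3 libraries at 569 to 577 names had totals from 176789 to 552833 counts.

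In serum, no miRNA changed past the threshold after surgery. The list of names that can match fragments of other abundant RNAs passed as higher by camera with the preset correlation (adjusted p = 0.0355), but not with an estimated correlation (adjusted p = 0.910). Of 17 tested members of that list, 14 were higher after surgery (median log2 fold change 1.10), 6 of them at an unadjusted p under 0.05. Among the members, miR-4488 had a log2 fold change of 2.72 (SE 1.12), miR-6090 of 2.33 (SE 1.02), miR-4532 of 1.94 (SE 0.805) and miR-663a of 1.76 (SE 0.770), all with an adjusted p of 0.581 (edgeR, n = 3 and 5). miR-1915-3p, which belongs to no list and was chosen after its values were seen, had 11.7% ± 13.2 of counts after and 2.13% ± 1.62 before surgery (log2 fold change 2.73, SE 1.14, adjusted p = 0.581). It ranged from 1.2% in animal F to 26.6% in animal D (Wilson 95% interval 26.5 to 26.7) after surgery.

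For this list of other small RNA fragments, the adjusted p with the preset correlation was 0.605 without serum of animal D after surgery. It was 0.127 without animal C before surgery and 0.0673 without animal B before surgery. With the sets of shared zeros as a term the direction turned (adjusted p = 0.708). That fit rests on animal B before against animals E and F after surgery, since no other set held serum of both times. No list member passed when adjusted over the list alone in serum, in EVs, between EVs and serum before surgery or in the interaction.

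By edgeR, 0 of 696 names passed in serum, with 54 at an unadjusted p under 0.05 (29 higher and 25 lower) where 34.8 would come by chance. DESeq2 and limma-voom also called 0. The smallest adjusted p was 0.581. In simulated data with the spread of these libraries, the same test called 29.1% of 4-fold and 78.8% of 16-fold changes among names kept by the filter. With a small spread it called 100% of both. With no filter on low counts, miR-6743-3p and miR-6813-3p passed (adjusted p = 0.0446).

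The miRNAs with the smallest p in serum are given here by direction. miR-6743-3p (log2 fold change 3.84, SE 1.03) had 5004 counts in animal D after surgery and 43 to 149 in the other 7 serum libraries. miR-6813-3p (3.82, SE 1.07) had 1754 counts in that library and 6 to 89 in the others. miR-6836-3p (3.06, SE 0.867), miR-6821-5p (2.47, SE 0.751), miR-1247-5p (2.03, SE 0.643) and miR-1469 (1.62, SE 0.557) completed those with higher values. On the lower side, miR-3913-3p, miR-4661-5p, miR-32-5p, miR-18b-5p and miR-1270 were listed at 0 in all 3 libraries after surgery and in animal B before it, and had 9 to 65 counts in the other 4 libraries. miR-19a-3p, of the miR-17 to miR-92 cluster, had 4 to 24 counts after and 24 to 88 before surgery (−2.05, SE 0.712).

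Marker lists of blood cells and tissues did not pass in serum. All 9 red blood cell miRNAs lay below 0 (median −1.44), as did 6 of 7 endothelial (−0.96), 6 of 7 platelet (−0.66), 5 of 8 myeloid (−0.22) and all 5 lymphoid miRNAs (−0.54). Liver (0.20), heart and skeletal muscle (0.096) and epithelium (0.11) had medians above 0. miR-133a-3p, a muscle miRNA, had 1.29 (SE 0.752), miR-208b-3p, expressed from a heart myosin gene, 0.096 (SE 0.765), miR-122-5p 1.09 (SE 1.24) and miR-200c-3p, an epithelial miRNA, 1.98 (SE 0.686). Medians were −0.38 for fibrosis, −0.18 for inflammation, −0.59 for hypoxia, −0.38 for the let-7 family, −1.27 for the miR-17 to miR-92 clusters, −0.14 for the miR-320 family, −0.029 for the imprinted 14q32 cluster and −0.89 for the primate chromosome 19 cluster. Adjusted p for these lists ran from 0.407 to 0.947. The hypoxia, let-7 and 14q32 lists had a median below 0 but a camera direction upward. The 2 smooth muscle members had a median of −0.83 and the single tested neuron member had −0.72, without a test. Without serum of animal D before surgery, the library of the lowest total in serum, the red blood cell (0.0318), endothelium and miR-17 to miR-92 (0.0266 each) lists passed as lower with the preset correlation, but not with an estimated correlation (adjusted p = 0.777 each). Endothelium passed without animal F after surgery (0.0191, and adjusted p = 0.852 with an estimated correlation) and the red blood cell list with the shared zeros as a term (0.0364, and 0.732). The fit with that term rests on animal B before against animals E and F after surgery. Among names above 0 in all 8 libraries red blood cell and endothelium (0.0451 each) and miR-17 to miR-92 (0.0126) passed, where the adjusted p with an estimated correlation was 0.719 for each.

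In EVs, no miRNA changed past the threshold after surgery. The miR-320 family passed as higher by camera with the preset correlation (adjusted p = 0.0318), but not with an estimated correlation (adjusted p = 0.885). Of its 5 tested members, 4 were higher after surgery (median log2 fold change 0.91). miR-320b, whose family is processed without the usual nuclear cleavage by Drosha, had 1.49 (SE 0.628), miR-320c 1.30 (SE 0.644), miR-320d 0.91 (SE 0.605) and miR-320a 0.74 (SE 0.658), with an adjusted p of 0.999 for each (edgeR, n = 3 and 5). The share of miR-320b in EVs was 0.286% ± 0.148 after and 0.166% ± 0.0656 before surgery. The liver miRNA miR-122-5p had a log2 fold change of 3.32 (SE 1.23, adjusted p = 0.999), with shares after surgery of 13.3% in animal D (Wilson 95% interval 13.2 to 13.4), 18.4% in animal E (18.3 to 18.6) and 0.641% in animal F (0.592 to 0.695). The shares before surgery ran from 0.0899% to 7.97%.

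The call of the miR-320 family with the preset correlation was lost without any 1 of 6 libraries, namely animals A (0.0726), B (0.0585), C (0.0847) or E (0.112) before surgery and animals D (0.616) or E (0.307) after it. It was also lost under library totals (0.0924), among names above 0 in all 8 libraries (0.0778), with the shared zeros as a term (0.124) and within the 5 EV libraries that share zeros (0.134).

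By edgeR, 0 of 856 names passed in EVs, with 15 at an unadjusted p under 0.05 (12 higher and 3 lower) where 42.8 would come by chance. DESeq2 and limma-voom called 0. The smallest adjusted p by edgeR was 0.999, and 0.0576 with the animal as a block. Among names kept by the filter, simulated changes with this spread were called in 22.8% of cases at 4-fold and 85.3% at 16-fold. With a small spread 100% of both were called. The names with the smallest p included piRNAs, small RNAs best known for silencing transposons in the germ line. piR_017723 had a log2 fold change of 2.84 (SE 0.856), with 1040 counts in animal D after surgery and 20 to 87 in the other 7 EV libraries. piR_017724 (2.22, SE 0.779), piR_001312 (2.18, SE 0.736) and piR_018570 (1.61, SE 0.564) were also on the higher side, with miR-3154 (2.36, SE 0.820) and miR-127-3p of the 14q32 cluster (1.80, SE 0.661). On the lower side stood miR-5197-3p (−2.07, SE 0.950), miR-6716-3p (−1.67, SE 0.787), miR-4454 (−1.64, SE 0.730), miR-3609 (−1.39, SE 0.568), miR-3200-3p (−1.29, SE 0.580) and miR-2909 (−1.21, SE 0.563).

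Of the other lists in EVs, all 4 heart and skeletal muscle members lay above 0 (median 0.56), as did 8 of 9 let-7 members (0.30) and 12 of 17 other small RNA fragments (0.32). All 4 epithelial (−0.64) and all 3 neuron members (−0.54) lay below 0. Medians were −0.56 for red blood cell, 0.18 for liver, −0.0083 for endothelium, 0.076 for platelet, −0.59 for myeloid, −0.39 for lymphoid, −0.081 for fibrosis, −0.081 for inflammation, −0.56 for the miR-17 to miR-92 clusters, −0.051 for 14q32 and −0.34 for the chromosome 19 cluster. Adjusted p ran from 0.0975 for let-7 to 0.978. The red blood cell, lymphoid and 14q32 lists had a median below 0 but a camera direction upward. Smooth muscle (−0.68) and hypoxia (−0.17) had 2 tested members each and no test. With the animal as a block, the red blood cell, heart and skeletal muscle, and other small RNA fragments lists passed upward and the myeloid list downward, each with an adjusted p of 0.0401, and of 0.860 with an estimated correlation. That fit compares the times only within animals D and E and leaves little to estimate the spread. The red blood cell list also passed upward without animal C before surgery (0.00902), with the shared zeros as a term (0.00113) and within the 5 EV libraries that share zeros (0.00197), where the adjusted p with an estimated correlation was 0.828, 0.986 and 0.953. EVs of animal C before surgery held 58.0% red blood cell miRNAs against 16.1% to 25.6% in the other 4. Epithelium passed downward without animal A before surgery (0.0497, and adjusted p = 0.902 with an estimated correlation). Liver (0.0210), let-7 and other small RNA fragments (0.0146 each) passed upward without animal F after it, with an adjusted p of 0.576 each with an estimated correlation. The let-7 family also passed upward without animal D before surgery (0.0126), with the shared zeros as a term (2.36e-04) and within the 5 EV libraries that share zeros (0.0114), and its adjusted p with an estimated correlation was 0.941, 0.986 and 0.953. The term for shared zeros and the fit within that set compare the times in the same 5 libraries. For the red blood cell and let-7 lists they are therefore not separate evidence.

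Before surgery, EVs and serum differed in 23 of 768 names in the fit without the animals, 21 higher and 2 lower in EVs. With the animal as a block 0 passed (edgeR, smallest adjusted p = 0.335, 102 at an unadjusted p under 0.05 where 38.4 would come by chance). All 21 higher in EVs were listed at 0 in all 5 serum libraries before surgery and had 5 to 185 counts in each EV library, so no fold is given. They included miR-4677-5p (20 to 185 counts in EVs), miR-105-3p (17 to 91), miR-1914-5p, miR-3146, miR-3185, miR-452-5p, miR-4538, miR-4660, miR-4758-5p, miR-5585-5p, miR-6731-5p and miR-6779-3p, each with an adjusted p of 0.0134 (edgeR, n = 5 and 5). Of the 21, 11 had 2 to 46 counts in serum of animal D after surgery and the other 10 were at 0 in every serum library. The 2 lower in EVs were piRNAs. piR_004987 fell by 2.76 on the log2 scale (SE 0.699, adjusted p = 0.0488) and piR_017723 fell by 2.53 (SE 0.611, adjusted p = 0.0355). Under library totals these were −1.18 and −1.10 and did not pass (adjusted p = 0.435 and 0.522), and neither passed without animal C in serum or without animal A, B, D or E in EVs (adjusted p = 0.0557 to 0.152). piR_004987 also missed the threshold without animal E in serum (0.0521).

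Red blood cell miRNAs were lower in EVs than in serum before surgery as a group, with 8 of 9 below 0 (median −1.61, adjusted p = 0.0157). Its adjusted p with an estimated correlation was 0.492. The share of the list was 28.1% ± 17.1 of counts in EVs and 43.8% ± 17.3 in serum (n = 5 each, exact permutation p = 0.175, adjusted p = 0.560 over the 28 whole-library tests). miR-92a-3p had a log2 fold change of −2.37 (SE 0.8, adjusted p = 0.183), miR-486-5p −2.13 (SE 1.09), miR-25-3p −1.88 (SE 0.953) and miR-16-5p −1.61 (SE 0.975). These 4 stayed below 0 under library totals, but the size of the change depends on the scaling. Mean shares in EVs and serum were 0.991% and 1.87% for miR-92a-3p, 13.6% and 26.4% for miR-486-5p and 10.5% and 12.3% for miR-16-5p. The mean share of miR-451a went the other way (1.24% in EVs and 0.911% in serum), with 4.51% in EVs of animal C. The call was lost without serum of animal B (0.120) or C (0.111) or EVs of animal A (0.117), B (0.0620) or E (0.0679).

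Several other lists lay lower in EVs before surgery, relative to the TMM centre, without passing. These were endothelium (6 of 7 below 0, median −0.65), platelet (7 of 7, −0.68), lymphoid (4 of 5, −1.21), fibrosis (6 of 7, −0.70) and let-7 (9 of 9, −0.57), each with an adjusted p of 0.0802. The median over all names was 0.35 under TMM and 1.04 under library totals, so directions at medians of this size can depend on the scaling. Mean shares of counts were higher in EVs than in serum for let-7b-5p (2.81% and 2.02%), miR-126-3p (0.707% and 0.272%) and miR-21-5p (1.06% and 0.607%). They were lower in EVs for miR-150-5p (0.926% and 1.40%) and miR-342-3p (0.559% and 0.906%). miR-191-5p, a platelet list member, had a log2 fold change of −2.17 (SE 0.823), and the lymphocyte miRNAs miR-342-3p and miR-150-5p had −1.90 (SE 0.711) and −1.61 (SE 0.820). The primate chromosome 19 cluster had all 6 members above 0 (median 1.29, adjusted p = 0.0895). Medians were −0.39 for liver, −0.41 for heart and skeletal muscle, −0.27 for myeloid, −0.63 for the miR-17 to miR-92 clusters, −0.70 for miR-320, −0.86 for epithelium, 1.49 for neuron, 0.14 for 14q32 and −0.34 for other small RNA fragments, with adjusted p from 0.0895 to 0.761. Inflammation had a median of 0.29 and a camera direction downward. The 2 smooth muscle (−0.95) and 2 hypoxia (0.17) members were not tested. When serum of animal D was left out, endothelium (0.0229), platelet and let-7 (0.0179 each), lymphoid (0.0232), fibrosis (0.0413) and miR-17 to miR-92 (0.0257) passed as lower, but not with an estimated correlation (adjusted p = 0.370, and 0.424 for miR-17 to miR-92). Leaving out serum of animal A, lymphoid, fibrosis and epithelium passed as lower (0.0496 each, and adjusted p = 0.481 with an estimated correlation). Without EVs of animal D, endothelium, lymphoid, fibrosis and let-7 passed as lower and the chromosome 19 cluster as higher (0.0439 each, and adjusted p = 0.448 with an estimated correlation). Without the EVs of both animals C and D, endothelium and fibrosis (0.0461 each), lymphoid (0.0425) and miR-17 to miR-92 (0.0488) passed as lower, with an adjusted p of 0.498 each with an estimated correlation.

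For the same comparison, DESeq2 called 54 (28 higher and 26 lower in EVs) and limma-voom 151 (106 and 45), and library totals gave 22, all higher. The count of calls was 55, 52, 49, 89 and 56 without serum of animal A, B, C, D and E in turn, 53 without EVs of animal C, and 0 of 393 among names above 0 in all 10 libraries (75 at an unadjusted p under 0.05). Over all 768 names in the main fit, 107 had an unadjusted p under 0.05 (edgeR, 51 higher and 56 lower in EVs) where 38.4 would come by chance. In data simulated with the fitted spread of these libraries, 25.9% of 4-fold and 88.3% of 16-fold changes were called among names kept by the filter. With a small spread it was 100% of both.

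After surgery, no name passed between EVs and serum. miR-150-5p had a log2 fold change of −2.45 (SE 0.704, adjusted p = 0.187, edgeR, n = 3 and 3) and passed when adjusted over the list alone, as the only lymphoid member. miR-200b-3p, an epithelial miRNA, was listed at 0 in the 3 EV libraries and had 24 to 67 counts in serum, and was the only epithelial member to pass when adjusted over the list alone (adjusted p = 0.145 over all names). miR-92a-3p had −2.07 (SE 0.627), miR-125a-5p −2.73 (SE 0.802) and miR-1306-5p −2.09 (SE 0.553, adjusted p = 0.145). miR-4251 had 24 to 110 counts and miR-617 34 to 47 counts in EVs, and both were listed at 0 in the 3 serum libraries, as were miR-4999-3p, miR-618 and miR-664b-5p. miR-4529-5p had 30 to 115 counts in EVs and 2 counts in 1 serum library, and miR-6846-3p was listed at 0 in EVs.

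No list passed after surgery in EVs against serum. The lowest adjusted p were 0.0882 for epithelium (median −0.82) and 0.181 for red blood cell (−0.88) and other small RNA fragments (15 of 19 below 0, −1.41). Medians were 0.010 for liver, −0.32 for heart and skeletal muscle, −0.23 for endothelium, −0.17 for platelet, −0.38 for myeloid, −1.03 for lymphoid, −0.24 for fibrosis, −0.32 for inflammation, −0.030 for let-7, −0.29 for the miR-17 to miR-92 clusters, 0.37 for miR-320, 2.03 for neuron, 0.11 for 14q32 and 2.09 for the chromosome 19 cluster. Liver, miR-320 and 14q32 had a median above 0 and a camera direction downward. Smooth muscle (−0.75) and hypoxia (0.79) were not tested. Without serum of animal D, myeloid (0.0486) and epithelium (0.00171) passed as lower, but not with an estimated correlation (adjusted p = 0.481 each). Epithelium passed as lower without EVs of animal E (0.0103, and adjusted p = 0.636 with an estimated correlation) and other small RNA fragments without serum of animal F (0.0191, and 0.832).

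By edgeR, 0 of 747 names passed after surgery, with 60 at an unadjusted p under 0.05 (39 higher and 21 lower in EVs) where 37.35 would come by chance. DESeq2 called 41 (35 and 6) and limma-voom 42 (36 and 6). Without serum of animal D, which was the only serum library after surgery outside the set with 524 shared zeros, edgeR called 251 (241 higher and 10 lower), while leaving out any other library gave 0. With the fitted spread, simulated 16-fold changes were called in 9.52% of cases and 4-fold changes in 1.30%, among names kept by the filter. With a small spread both were called in 100% at the same group size.

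Across 1018 names, the log2 ratio of EVs to serum before surgery correlated with that after surgery (Pearson r = 0.775, Spearman rho = 0.776). The r was 0.617 over the 375 names above 0 in all libraries. Names are not independent replicates, and animals D and E enter both ratios. For the log2 ratio after to before surgery, serum and EVs gave r = 0.111 and rho = 0.0877 over the same names. That r was 0.236 in animals D and E alone and 0.242 over the 375 names.

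**Figure D3:**
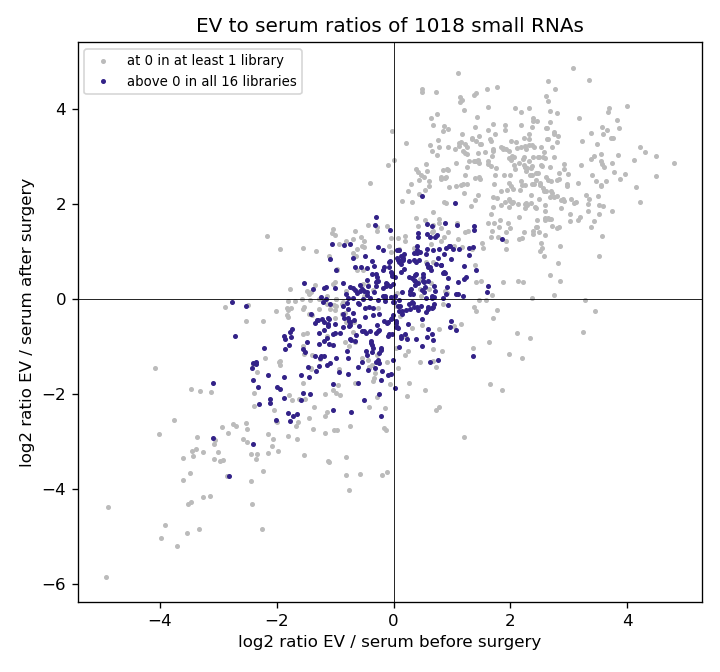
Log2 ratio of EVs to serum before surgery (x axis) against the same ratio after surgery (y axis) for 1018 names. Dark points are the 375 names above 0 in all 16 libraries (r = 0.617) and grey points are names at 0 in at least 1 library.

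Whether the response to surgery differed between EVs and serum was tested as an interaction, and no miRNA passed. The miR-320 family had the highest median among the lists above 0 (1.38 on the log2 scale, 4 of 5 above 0, adjusted p = 0.688), and miR-320b had a difference of 1.80 (SE 1.01, adjusted p = 0.696, edgeR). miR-122-5p had a difference of 2.38 (SE 1.98, adjusted p = 1.00) and miR-6743-3p one of −4.29 (SE 1.5, adjusted p = 0.443). miR-211-3p, miR-3913-3p, miR-617 and miR-1270 were listed at 0 in all 3 serum libraries after surgery and above 0 in all 8 EV libraries (adjusted p = 0.416), and miR-4529-5p and miR-323b-5p had the same sign and adjusted p. miR-409-5p, miR-4677-5p, miR-3934-3p, miR-200b-3p and miR-4660 had the opposite sign (adjusted p = 0.443).

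All 9 red blood cell (median 0.87), all 7 endothelial (0.82), 7 of 8 platelet (0.97) and 7 of 9 let-7 miRNAs (0.81) had interaction values above 0, and 5 of 7 epithelial (−0.95) and 15 of 19 other small RNA fragments (−0.84) had values below 0. None of these lists passed (lowest adjusted p = 0.42, for epithelium). Medians were 0.42 for liver, −0.26 for heart and skeletal muscle, 0.29 for myeloid, −0.22 for lymphoid, 0.26 for fibrosis, 0.26 for inflammation, 0.20 for hypoxia, 0.58 for the miR-17 to miR-92 clusters, 0.44 for neuron, −0.0018 for 14q32 and 0.19 for the chromosome 19 cluster. Liver, myeloid, inflammation and hypoxia had a median above 0 and a camera direction downward, and lymphoid the reverse. The 2 smooth muscle members (0.34) were not tested. Epithelium passed downward without serum of animal D after surgery (0.00956, and adjusted p = 0.971 with an estimated correlation).

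By edgeR, 0 of 1018 names passed the interaction test, with 85 at an unadjusted p under 0.05 (50 above and 35 below 0) where 50.9 would come by chance. DESeq2 called 3 and limma-voom 0. Leaving out serum of animal B before surgery, edgeR called 6, which included miR-211-3p, miR-3913-3p, miR-617, miR-1270 and miR-4529-5p.

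None of 28 tests on whole-library measures reached p = 0.05 in 2-sided exact permutation tests, and the lowest adjusted p over the 28 was 0.560. The share of the other small RNA fragments list in serum was 4.93% ± 4.16 (n = 3) after and 1.48% ± 0.688 (n = 5) before surgery (exact permutation p = 0.0536). After surgery it was 9.62% in animal D, 3.51% in animal E and 1.67% in animal F. In EVs before surgery the primate chromosome 19 cluster took 0.317% ± 0.197 of counts (n = 5) and in serum 0.0857% ± 0.123 (n = 5, exact permutation p = 0.0556). After thinning to 65537 counts, 887 ± 117 names were above 0 in EVs and 725 ± 115 in serum before surgery (n = 5 each, exact permutation p = 0.0714). That test ignores the animals. EVs and serum had 805 and 726 in animal A, 793 and 555 in B, 991 and 716 in C, 1036 and 876 in D and 808 and 753 in E. After surgery they had 903 and 806 in D, 802 and 553 in E and 781 and 557 in F, so EVs had more names above 0 in every animal. Before thinning, EVs of animal A had 805 and serum of animal B 577 names above 0 before surgery, so thinning changed these little. No set of shared zeros held both fractions. How names were listed therefore cannot be told apart from a difference between EVs and serum here. The 10 most abundant names held 44.8% ± 11.7 of counts in EVs and 60.8% ± 17.8 in serum before surgery (n = 5 each, exact permutation p = 0.151). The log2 ratio of miR-451a to miR-23a-3p, an index of red blood cell lysis, was 0.67 ± 1.48 in serum before (n = 5) and −0.049 ± 0.31 after surgery (n = 3, exact permutation p = 0.554). In EVs it was 0.27 ± 1.96 (n = 5) and 0.69 ± 0.71 (n = 3, exact permutation p = 0.786). The smallest p these tests allow was 0.0179 with 3 against 5 libraries, 0.00794 with 5 against 5 and 0.1 with 3 against 3, so the comparison after surgery could not reach 0.05.

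Leaving out single libraries took some of these tests under 0.05. In EVs against serum before surgery without serum of animal D, the exact permutation p was 0.0159 for names above 0 after thinning, 0.0159 for the 10 most abundant names and 0.0238 for the chromosome 19 cluster. The chromosome 19 cluster had exact permutation p of 0.0318 without EVs of animal C and 0.0397 without EVs of animal D, and the red blood cell share had 0.0318 without EVs of animal C. In serum after against before surgery, the share of other small RNA fragments had an exact permutation p of 0.0476 without animal F after surgery and 0.286 without animal D after surgery, which lowered the difference from 3.45 to 1.11 percentage points.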

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

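All tests of explanations in this part, the counts over other splits of the libraries included, were chosen after the results were seen.

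The 21 miRNAs higher in EVs than in serum before surgery, such as miR-4677-5p, were listed at 0 in all 5 serum libraries. Lower depth in serum as a whole is argued against by the totals before surgery, which summed to 1582854 counts in serum and 1063078 in EVs. At their EV shares each would have had 201 to 619 counts over these serum libraries. That test could hardly have failed, since the names were called for counts in EVs against 0 in serum, so it adds nothing on depth. A filter on low sums as the whole cause is argued against by the set of animals A and E, which listed sums from 1 upward and would have had at least 21.6 counts of each miRNA at its lowest EV share (5.83 with TMM scaling). The set with animal B listed sums over its 3 libraries from 24 upward. In serum of animal B alone, its only library before surgery, at least 38.0 would be expected but 6.17 with TMM scaling. Such a filter cannot be told apart from other causes there. A higher level in EVs cannot be told apart from names left out whatever their sum, as 0 sets of shared zeros held libraries of both fractions.

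In splits by shared zeros, setting serum of animal B before surgery with animals E and F after it against the other 5 gave 148 calls, 146 of them at 0 in all libraries of 1 side. Filtering in some form cannot be told apart from other causes there, since 0 of 453 names above 0 in all 8 serum libraries passed (edgeR, 14 at an unadjusted p under 0.05 where 22.7 would come by chance), but leaving out names at 0 removes those 146 by construction. Whether it was a filter on low sums stays open, as the 144 called names at 0 in that set would have had sums of 28.8 to 265 at the shares of the other libraries, above the 24 it listed at least, but 73 of them under 24 at the lowest of those shares. Setting EVs of animals C and D before and D after surgery against the other 5 EV libraries gave 152 calls. Filtering or depth as the whole cause is argued against, since 52 of 672 names above 0 in all 8 EV libraries passed and 108 of 781 passed after thinning. These fits took libraries as independent, although animals D and E entered both before and after surgery, so the counts of calls may be too high. A difference between these animals cannot be told apart from other sources, as 55.6% of these 52 that were also tested in serum (25 of 45, exact 95% interval 40 to 70.4) had the same direction in their serum.

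miR-122-5p, the hepatocyte miRNA, had a log2 fold change of 3.32 in EVs after surgery that did not pass. Scaling is argued against as the cause, since library totals gave 2.15 (SE 1.04). Spread between animals stays open, with an exact permutation p of 0.232 for its share in EVs and 0.179 in serum. Within animals its share was 10.2-fold (D) and 2.31-fold (E) higher after surgery in EVs and 2.55-fold and 3.98-fold in serum. More RNA from liver could not be decided, as the test run could only favour it or leave it open. The other 6 liver miRNAs had a median within-animal log2 change of −0.47 (SD 0.80) in EVs of animals D and E. Of these 12 changes, 1 was above 0, so as shares of counts they did not rise with miR-122-5p. The changes were taken on library totals with 10 CPM added. Under library totals, the median log2 fold change over all names in EVs was −0.55. Under TMM, 3 of the 6 tested liver members, miR-122-5p included, were above 0 (median 0.18). A fall of the liver miRNAs relative to other names was thus not shown.

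Where the real count was 0, every split gives at least as many calls, so the count of splits says nothing about chance. For serum after against before surgery these were 56 of 56 splits, with 148 calls in the highest other, and for EVs 56 of 56, with 152 in the highest other. Both highest splits follow the shared zeros, and such counts point to a structure apart from surgery, in the samples or in how names were listed. The interaction likewise had 0 calls and 56 of 56 splits, with 262 in the highest other. For EVs against serum before surgery, 2 of 100 drawn splits, the real one included, gave at least 23 calls and the highest other gave 37, so chance is excluded at the 0.05 level only against splits that ignore the animals. The 13 drawn splits that part all animal pairs, the real one included, are too few for a share under 0.05, and the highest other of these gave 0. With the animal as a block, 0 of the 23 passed (edgeR, smallest adjusted p = 0.335). For EVs against serum after surgery, the 10 splits are too few for a share under 0.05, and the real and the highest other count were both 0.

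Single libraries stood far from the rest of their group of 5 in 14 of 46 values tested, by the gap to the nearest library as a fraction of the group's range. The cutoff gives about 1 in 20 by chance for independent, normally distributed values. Most values here were shares that are skewed and overlap, as the red blood cell share, miR-486-5p and miR-451a do, so the count cannot be set against that rate. EVs of animal C before surgery stood high in the log2 ratio of miR-451a to miR-23a-3p (3.71 against −1.10 to −0.036, gap fraction 0.778), in the red blood cell share (58.0% against 16.1% to 25.6%, 0.772), in miR-486-5p (31.5% against 7.59% to 10.7%, 0.871) and in miR-451a (4.51% against 0.169% to 1.08%, 0.790). EVs of animal E before surgery stood high in miR-122-5p (7.97% against 0.0899% to 2.25%, 0.725) and miR-6090 (2.59% against 0.425% to 0.937%, 0.763). EVs of animal B stood high in miR-1915-3p (15.2% against 0.688% to 2.76%, 0.857), and EVs of animal D in the lymphocyte miRNA miR-342-3p (1.12% against 0.376% to 0.502%, 0.831) and the endothelial miRNA miR-126-3p (2.13% against 0.158% to 0.544%, 0.804). Serum of animal D before surgery had 30.0% of its counts in its 10 most abundant names against 63.5% to 74.6% (0.751) and 0.304% in the chromosome 19 cluster against 0.00597% to 0.0506% (0.850). Serum of animal C stood high in miR-16-5p (23.7% against 8.67% to 10.2%, 0.899), and serum of animal B in miR-122-5p (6.15% against 0.100% to 1.19%, 0.821) and miR-320a (0.382% against 0.172% to 0.230%, 0.724).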

How the results depend on the processing

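The fits with shared zeros as a term, with names above 0 in every compared library, within or without parts of the EV libraries, and without piRNAs were added after seeing the data. Counts of calls stayed within 1.5 times the reported value in 100 settings and moved in 23. Serum after against before surgery gave 2 calls with no filter and 0 otherwise, and EVs after against before gave 0 in every setting run. EVs against serum before surgery gave 23, which became 54 with DESeq2, 151 with limma-voom, 56 with no filter, 0 with a minimum count of 50, 0 with the replicate block, 150 with limma-voom and the animal as a random effect, 57 with all 16 libraries in 1 fit, 4 after thinning, 0 among names above 0 in all 10 libraries, 135 without the 3 EV libraries outside the shared-zero set, and 26 to 89 on leaving out 1 library. For the 21 names listed at 0, the loss under the minimum count of 50 and among names above 0 follows from construction, since both settings remove them. The 2 piRNAs stayed tested and missed the threshold (adjusted p = 0.143 each with the minimum of 50, and 0.0829 for piR_004987 and 0.0736 for piR_017723 among names above 0). For these and the other settings the cause was not tested. EVs against serum after surgery gave 41 with DESeq2, 42 with limma-voom, 41 with limma-voom and the random effect, and 0 to 251 on leaving out 1 library. The interaction gave 3 with DESeq2 and 0 to 6 on leaving out 1 library.

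The list of other small RNA fragments in serum reversed with the shared zeros as a term (adjusted p = 0.708), had 0.910 with an estimated correlation, and 1.14e-04 to 0.605 on leaving out 1 library. In serum, the fit with that term rests on animal B before against animals E and F after surgery. The miR-320 family in EVs had an adjusted p of 0.885 with an estimated correlation, 0.0924 under library totals, 0.0778 among names above 0, 0.124 with the shared zeros as a term, 0.134 within the shared-zero set, and 7.34e-05 to 0.616 on leaving out 1 library. The red blood cell list in EVs against serum before surgery had 0.492 with an estimated correlation and 8.53e-04 to 0.120 on leaving out 1 library. The cause was not tested. The animal as a block changed the 4 list calls in EVs and the 23 calls given in the report, and no other call.

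Of the settings for named miRNAs, 61 passed where the reported fit did not, 36 were lost, 5206 kept their side and 0 reversed. The sign of an uncalled value turned in 369 of 5303 settings. For lists, 48 passed anew, 21 were lost and 1237 kept their side, and for whole-library measures 7 passed anew and 231 kept theirs. None of the 48 passed with an estimated correlation in the same setting, which was added after seeing the data. Correlations of EV to serum ratios moved to 0.8 with animals D and E taken out before surgery and 0.617 over names above 0 in all libraries, and those of the surgery effects to 0.236 in animals D and E and 0.242 over those names. The depth of 65537 to 639207 counts limits names with few counts.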

Other observations

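The values in this part were singled out after seeing the data, and no test was planned for them.

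The let-7 family was abundant in all groups. let-7b-5p, an abundant member of this family of developmental timing miRNAs, took 2.02% ± 0.708 (SD, n = 5) and 1.94% ± 1.06 (n = 3) of serum counts before and after surgery, and 2.81% ± 0.844 (n = 5) and 3.75% ± 1.52 (n = 3) of EV counts. miR-126-3p, the main miRNA of endothelial cells, took 0.272% ± 0.146 and 0.106% ± 0.0732 in serum and 0.707% ± 0.815 and 0.281% ± 0.296 in EVs, in the same order. miR-150-5p, a miRNA of mature lymphocytes, took 1.40% ± 0.772 and 1.22% ± 0.527 in serum and 0.926% ± 0.726 and 0.444% ± 0.258 in EVs.

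Between EVs of animals C and D before and D after surgery and the other 5 EV libraries, 52 names above 0 in all 8 passed, 32 of them higher in animals C and D. The split was chosen from the shared zeros of the same counts. Its fit took libraries as independent, although animals D and E entered both before and after surgery, so its SEs may be too small. These included members of several lists, none tested for enrichment, with log2 differences of 3.80 (SE 0.814) for miR-451a (red blood cell), 3.13 (SE 0.708) for miR-142-3p (myeloid), 2.22 (SE 0.558) for miR-150-5p (lymphoid) and 2.10 (SE 0.486) for miR-222-3p (endothelium).

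The median count among names above 0 was 20 to 60 per library although totals ranged from 65537 to 639207 counts. The primate chromosome 19 cluster, a group of miRNA genes known from primates, had counts in these sheep libraries for 9 of its 68 listed names, and its share was 0.304% in serum of animal D before surgery, 0.00597% to 0.0506% in the other 7 serum libraries and 0.0743% to 0.600% in the 8 EV libraries. miR-1915-3p was the most abundant name in serum of animal D after surgery (26.6%), in EVs of animal D after surgery (16.3%) and in EVs of animal B before surgery (15.2%).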
